A study of Homo sapiens with 68 samples.

How the data were processed

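Human dendritic cells of 3 types were profiled by bulk RNA sequencing: Langerhans cell-derived dendritic cells (LCDC), myeloid dendritic cells (mDC) and monocyte-derived dendritic cells (moDC). Each type was cultured alone or with 1 of 6 strains of the skin bacterium Cutibacterium acnes for 24 h, per the labels' protocols, which do not say how long the cells alone were kept. Groups and replicate numbers came from the sample titles, and a title with no number counted as number 1. Every strain group held 3 libraries, and cells alone held 5 libraries in LCDC, 4 in mDC and 5 in moDC, 68 in all. RNA was isolated with a Quick-RNA Microprep kit, checked on a TapeStation and turned into libraries with the KAPA mRNA HyperPrep kit, per the labels' protocols. The titles give strain names only. Strains 43PA1, 5PA1 and 96PA1 were taken as acne-associated and 110PA3, 110PA4 and 42PA3 as healthy-associated from general knowledge of the species, not from the labels.

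The deposited values are read counts per gene, whole numbers that were not normalized, in 1 file per library with a single count column and 60664 gene identifiers. FastQC 0.11.9, Trimmomatic (version not given), STAR 2.7.9a and the build GRCh38 (hg38) are named in the submitters' processing notes. The gene annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap others, antisense genes and close paralogs could share reads and were avoided or named as such. Of the identifiers, 60463 matched a symbol in the gene name table, 58396 were present in GENCODE release 29 (used here for positions on GRCh38), and 15690 had 0 counts in every library. Total counts per library were 16.3 to 48.9 M in LCDC (median 24.6), 10.4 to 43.7 M in mDC (median 26.1) and 14.6 to 50.5 M in moDC (median 33.9).

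Differences were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filterByExpr rule by group with its minimum count of 10 and minimum total of 15, and the robust quasi-likelihood F test with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and each printed log2 fold change carries its standard error (SE) from the fit. Levels are counts scaled to 1 library size (CPM), given as mean ± SD over the libraries of a group and scaled within the libraries of that fit. Levels of single libraries are scaled over all 68, so the 2 differ somewhat. Each cell type was fitted alone for 4 questions: the mean of the 6 strains against cells alone, the genes called with 1 sign for all 6 strains, acne-associated against healthy-associated strains, and any difference among the 6 strains. Cells alone of the 3 types were fitted together to compare the types, and all libraries were fitted together for differences in the response between types. No label says whether replicates came from separate donors, cultures or days, so p-values measure only the spread between these samples, which may be technical.

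Before the data were examined, 42 lists covering 774 genes were fixed for cytokines, chemokines, maturation, interferon response, metabolism, stress and markers of other cell types. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation; adjusted p-values of lists are over the 42 lists of a comparison. Counts of called members are over all genes tested and, in those words, adjusted over the list alone. The rule for named genes, also fixed before the data were examined, took the 10 largest log2 fold changes in each direction among called genes with a symbol, at least 5 CPM in the higher group and 1 sign for each of the 6 strains. It added up to 4 called members of each list past the threshold and 21 genes that were always reported, such as IL1B, TNF, CD83 and CCR7; where nothing was called it took the 3 genes with the lowest p. Genes outside the rule are said to be chosen after their values were seen. Sex-linked marker genes, genes that vary in copy between people and antigen receptor segments were never named. A fold against a group with 0 counts is given as a lower bound from a floor of 3 counts over the group, and a ratio against 1 to 3 counts with its 95% interval; both cover counting error only.

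The test was tried on simulated counts drawn from the real means, library sizes and spreads, with 200 genes changed, 100 of them by 2-fold and 100 by 4-fold. For strains against cells alone, 52% of 2-fold and 86% of 4-fold changes were recovered in LCDC (18304 genes tested), 3% and 53% in mDC (18551 genes), and 23% and 84% in moDC (18835 genes). For acne-associated against healthy-associated strains the shares were 56% and 90% in LCDC (18332 genes), 20% and 87% in mDC (18463 genes), and 43% and 90% in moDC (18890 genes). For any difference among the strains they were 14% and 67% in LCDC (18219 genes), 0% and 25% in mDC (18452 genes), and 0% and 51% in moDC (18882 genes). Between cells alone they were 5% and 65% for LCDC against moDC (16260 genes), 3% and 65% for LCDC against mDC (16260 genes), and 1% and 57% for moDC against mDC (16217 genes). For the difference in response they were 14% and 71% for LCDC against moDC and 6% and 64% for LCDC against mDC (21054 genes). False calls numbered 0 to 9 in each simulation. The simulated counts held no pairing by replicate number and no difference between the 2 sets of libraries described below. These shares and false calls therefore describe the test on independent libraries, and those of the real libraries may differ.

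Same-numbered strain libraries deviated from their group means together in LCDC (45 of 45 pairs of libraries over a correlation of 0.1, lowest 0.61) and in moDC (45 of 45, lowest 0.30), but not in mDC (31 of 45, lowest −0.33) and not between cells alone and strains. The numbers therefore pair the strain libraries of LCDC and moDC with each other, from the data and not from a label. Replicate libraries were compared with a chi-square test of their counts over genes with at least 20 counts in the pair: over 80 pairs the statistic per degree of freedom was 3 to 664 with a median of 291, and the lowest values belonged to pairs among the LCDC cells alone numbered 2 to 5. These LCDC libraries stayed above counting noise and were kept as separate libraries, with an alternative that sums them into 1. The next lowest value was 19, for moDC cells alone 2 and 5, which were not summed. Other pairs of moDC alone lay at 102.6 or more.

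The libraries fell into 2 sets by a measure that is not a group label, the counts of processed pseudogenes (10171 in the files), which copy the messenger RNA of highly used genes. In 33 libraries the pseudogene MTCO1P40 lay at 0 to 0.936 CPM, and in the other 35 at 13.3 to 34.9 CPM. The first set (10.4 to 24.4 M counts) held all 14 cells alone libraries and 19 strain libraries: the 18 numbered 1 and mDC with 110PA3 number 2. The second set (24.6 to 50.5 M counts) held the other 35 strain libraries and no cells alone, so no comparison with cells alone could be made within it. Comparisons with cells alone were repeated within the first set. For strains against cells alone in 1 cell type, first-set counts of gene lists stand beside the pooled ones. For genes named for 1 cell type, values are given where the call or its direction differed and for some others. List counts of differences in response and of genes shared by strains or by cell types are from all libraries only. Other alternatives, chosen before or after the data were seen as stated in the closing section, were RLE size factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, leaving out each library, only libraries of 1 number, and thinning every library to the smallest total. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.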

Results

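Bulk RNA sequencing was used to ask how 3 kinds of human dendritic cell, the cells that carry antigen to T cells, respond to strains of Cutibacterium acnes, a skin bacterium found on healthy and on acne-prone skin. Langerhans cell-derived (LCDC), myeloid (mDC) and monocyte-derived (moDC) dendritic cells were measured alone and after 24 h with 110PA3, 110PA4, 42PA3, 43PA1, 5PA1 or 96PA1. Each strain had 3 libraries per cell type, and cells alone had 5, 4 and 5 in the order given. The 68 libraries held 10.4 M to 50.5 M counts. All cells alone libraries and 19 of the strain libraries belonged to a first set with few processed pseudogene counts, and the other 35 strain libraries to a second set without any cells alone. First-set counts therefore stand beside the pooled counts of gene lists for strains against cells alone in 1 cell type. List counts of differences in response and of genes shared by strains or by cell types are pooled only. For genes named for 1 cell type with strains against cells alone, a first-set value is given where the call or its direction differed, and for some others. Group means in CPM are scaled within the libraries compared, and levels of single libraries over all 68, so the scales differ somewhat.

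With any of the strains, LCDC carried far more of the transcripts of dendritic cell maturation and migration than LCDC alone. CCR7, the receptor that guides dendritic cells to lymph nodes (ENSG00000126353, chromosome 17, 40553769 to 40565472 of GRCh38), lay at 1427 ± 681 CPM with strains (SD, n = 18) and 27.8 ± 56.2 CPM in cells alone (n = 5). Its log2 fold change was 5.67 ± 1.13 (SE, adjusted p = 0.000839). CD83, a surface marker of mature dendritic cells (ENSG00000112149, chromosome 6, 14117256 to 14136918), rose by 3.79 ± 0.68 to 2567 ± 1065 CPM. CCL22, a chemokine that draws regulatory and type 2 helper T cells, rose by 6.41 ± 0.93 to 7548 ± 4609 CPM, and IDO1, which breaks down tryptophan, rose by 4.04 ± 0.58. In the first set alone the log2 fold changes were 6.03 ± 1.27 for CCR7, 3.75 ± 0.71 for CD83, 4.21 ± 0.45 for CCL22 and 4.63 ± 0.46 for IDO1. The cells alone library numbered 1 carried most of the cells alone means: CCR7 lay at 113 CPM there and at 1.98 to 3.48 CPM in numbers 2 to 5, and CD83 at 590 CPM and at 54.6 to 63.4 CPM. Leaving out 1 library moved CCR7 to between 5.37 and 9.04 and CD83 to between 3.57 and 5.32, and with cells alone 2 to 5 summed CD83 stood at 2.80 (adjusted p = 0.0520). Of the 27 maturation genes tested, 24 rose and 0 fell (24 adjusted over the list alone), with a median log2 fold change of 3.62. The camera test of that list gave an adjusted p of 1.91e-15, and adjusted p = 0.0456 with an estimated correlation. Among first-set libraries 22 of 26 rose and 2 fell (adjusted p = 0.415 with an estimated correlation).

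Targets and feedback regulators of NF-kB, the transcription factor downstream of microbial sensors, also rose in LCDC: 19 of 23 (19 adjusted over the list alone), median 2.06, camera adjusted p = 7.77e-12, but adjusted p = 0.116 with an estimated correlation. Within the first set 16 of 22 rose and 1 fell, where the list passed (adjusted p = 0.0335 with an estimated correlation). Among them were BIRC3, an inhibitor of cell death (4.14 ± 0.96), and the adaptor TRAF1 (3.99 ± 0.46). T helper polarising cytokines rose in 7 of 12 and fell in 1 (9 adjusted over the list alone, and 1 lower, adjusted p = 0.353 with an estimated correlation; 4 higher and 2 lower of 8 in the first set), with EBI3, a subunit of interleukin 27 and 35, at 6.17 ± 1.13. IL12B, the p40 subunit of interleukins 12 and 23, rose by 4.99 ± 1.55 over all libraries, but that rise rested on the second set. It lay at 5.37 to 53.3 CPM there and at 0.281 to 4.81 CPM in the strain libraries of the first set, against 2.17 CPM in cells alone number 1. It had too few counts in the first set to be tested. CXC chemokines rose in 8 of 13 (11 adjusted over the list alone, adjusted p = 0.496 with an estimated correlation; 3 higher and 0 lower of 7 in the first set). CXCL8, a neutrophil attractant, stood at 2.89 ± 0.97 over all libraries (adjusted p = 0.0245), at 2.93 (adjusted p = 0.0534) without the cells alone library numbered 3, and at 1.05 ± 0.42 within the first set (adjusted p = 0.0508). Cholesterol synthesis enzymes rose in 12 of 22 (12 adjusted over the list alone, median 0.62, camera adjusted p = 0.00127, adjusted p = 0.496 with an estimated correlation). SQLE, the squalene epoxidase, rose by 1.68 ± 0.22, and in the first set 7 rose and 3 fell, with a median of 0.20. Glycolysis genes rose in 11 of 24 (14 adjusted over the list alone, adjusted p = 0.496 with an estimated correlation; 10 higher and 3 lower of 24 in the first set), for example ALDOC (1.92 ± 0.43). HMOX1, which degrades heme under oxidative stress, rose by 2.12 ± 0.31.

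Other LCDC transcripts fell with the strains. TNF, the inflammatory cytokine (ENSG00000232810, chromosome 6, 31575567 to 31578336), went from 89.2 ± 38.6 CPM in cells alone to 17.6 ± 15.2 CPM, a log2 fold change of −2.38 ± 0.57 (adjusted p = 0.00351) and −2.77 ± 0.37 within the first set. In single libraries it lay at 18.1 CPM in cells alone number 1, near the strain libraries numbered 1 (7.36 to 16.6 CPM). That is within the range of all strain libraries (2.7 to 50.5 CPM). Cells alone 2 to 5 lay at 91.3 to 102 CPM, and both falls rest on them. They were near copies of each other that the fit counts as separate libraries, so the SE and p of TNF are too small to that extent. CD1A, a lipid antigen-presenting molecule typical of Langerhans cells, fell by −1.92 ± 0.26, while CD207 (langerin) stood at −0.71 ± 0.42 (adjusted p = 0.187) over all libraries and at −1.95 ± 0.39 (adjusted p = 0.00132) within the first set, where it was low in cells alone number 1 as well (1390 CPM, the next at 3210 CPM). Pattern recognition receptors fell in 11 of 26 (13 adjusted over the list alone, median −0.88, camera adjusted p = 0.00141, adjusted p = 0.524 with an estimated correlation; 0 higher and 14 lower of 25 in the first set), among them the beta-glucan receptor CLEC7A (−1.56 ± 0.18) and the scavenger receptor MSR1 (−2.54 ± 0.63, but −1.08 (adjusted p = 0.175) without the cells alone library numbered 1). Eicosanoid enzymes fell in 7 of 13 and rose in 2 (7 adjusted over the list alone, and 2 higher, adjusted p = 0.496 with an estimated correlation; 2 higher and 9 lower of 13 in the first set): ALOX5, which starts leukotriene synthesis, fell by −1.83 ± 0.15 and the prostaglandin D synthase HPGDS by −2.46 ± 0.19. AXL, a receptor for dying cells, fell by −3.07 ± 0.43. The cell adhesion genes CHL1 (−6.51 ± 0.82) and CXADR (−4.81 ± 0.28) fell as well. The costimulatory genes CD80 (−0.50 ± 0.48, adjusted p = 0.435) and CD86 (−0.11 ± 0.16, adjusted p = 0.633) did not pass the test, but CD80 stood at −1.86 ± 0.45 (adjusted p = 0.00424) within the first set.

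In total 7064 of 18815 genes passed in LCDC, 3773 higher and 3291 lower, of which 2781 and 1782 differed by at least 2-fold. Processed pseudogenes made up 658 of the higher and 69 of the lower calls, against 130 and 36 within the first set. Markers of platelets and red cells moved with the strains too: 5 of 7 were higher (5 adjusted over the list alone, adjusted p = 0.496 with an estimated correlation; 1 higher and 0 lower of 3 in the first set), for example GP1BA (6.16 ± 1.03). Ribosomal protein genes did so in 6 of 30, all higher (0 adjusted over the list alone, adjusted p = 0.716 with an estimated correlation), but in 29 of 30 within the first set (median 1.30, adjusted p = 0.671 with an estimated correlation). There 19 of 27 cell cycle genes fell and 2 rose (camera adjusted p = 0.00107, adjusted p = 0.671 with an estimated correlation), against 0 and 2 over all libraries. Within the first set 8031 of 15052 genes passed (3830 higher, 4201 lower), 4495 of the 7064 among them. Both counts use the same cells alone and first-set libraries, which raises that share in each cell type. With separate cells alone for each set, 77.8% or 84.7% of the genes called in the second set of LCDC had the same sign in the first, depending on the split, against 53.2% or 56.2% of genes with an adjusted p over 0.5. Near copies among cells alone 2 to 5 lay in both parts of that split, so the parts were not independent. All first-set strain libraries of LCDC are numbered 1, so strains and number were not told apart for any first-set value of LCDC. The LCDC cells alone numbered 2 to 5 were near copies of each other, and with their counts summed into 1 library 1490 genes passed.

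**Figure D1:**
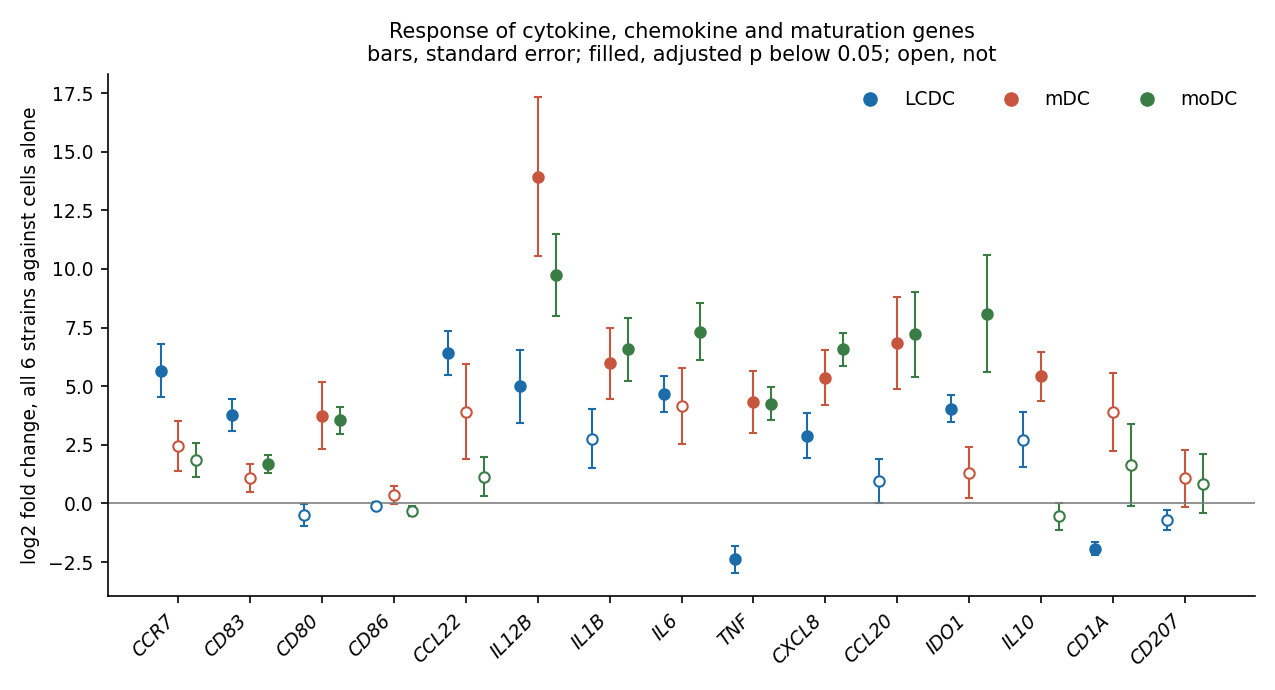
Log2 fold change of selected genes with all strains against cells alone in LCDC, mDC and moDC; points are estimates, bars are 1 SE, and filled points have an adjusted p under 0.05. TNF lies below 0 in LCDC and above 0 in mDC and moDC.

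In mDC the strains brought out transcripts that were almost absent from cells alone. IL12B (ENSG00000113302, chromosome 5, 159314783 to 159330887) lay at 524 ± 516 CPM with strains (n = 18) and 0.0260 ± 0.0312 CPM in cells alone (n = 4), where 2 counts in all were found; the ratio was 22600 with a 95% counting interval of 6260 to 187000. These values came from the second set, at 277 to 1470 CPM: the strain libraries of the first set lay at 0.274 to 12.4 CPM, a log2 fold change of 7.08 ± 1.45 (adjusted p = 0.00819). The elastase MMP12 was at least 4920-fold higher and the chemokine CCL1 at least 1190-fold higher than the limit set by 0 counts in cells alone, though CCL1 did not pass within the first set (adjusted p = 0.0590). CCL19, the ligand of CCR7, rose by 9.72 ± 1.45, and the eosinophil attractant CCL24 by 11.15 ± 1.49. The cytokines IL1B (5.98 ± 1.51), IL10 (5.42 ± 1.03) and IL23A (6.10 ± 1.45) rose over all libraries and within the first set (3.52 ± 1.06, 4.05 ± 0.95 and 3.38 ± 0.97). TNF stood at 4.31 ± 1.32 over all libraries (adjusted p = 0.0182), at 4.04 (adjusted p = 0.0676) without the cells alone library numbered 2, and at 1.75 ± 0.88 within the first set (adjusted p = 0.178).

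In mDC maturation genes rose in 13 of 27 and fell in 1 (15 adjusted over the list alone, and 1 lower), median 2.61, camera adjusted p = 1.23e-13, adjusted p = 0.355 with an estimated correlation (6 higher and 0 lower of 27 in the first set). The interleukin 2 receptor IL2RA rose by 6.33 ± 1.09 and the checkpoint ligand PDCD1LG2 by 5.32 ± 1.06. CCR7 (2.46 ± 1.07, adjusted p = 0.0834) and CD83 (1.09 ± 0.58, adjusted p = 0.152) did not pass the test, but the cells alone library numbered 1 carried both at the level of the strain libraries. Without it CCR7 stood at 7.94 (adjusted p = 1.47e-07) and CD83 at 2.74 (adjusted p = 0.000414), 25 maturation genes passed, all higher, and 15 interferon-stimulated genes passed, all higher. For these genes that library lay at median positions of 0.92 and 2.18, from 0 at the other cells alone to 1 at the strain libraries. By its label it had no bacteria, so these rises were not told apart from a difference among cells alone. NF-kB targets rose in 13 of 23 and fell in 1 (15 adjusted over the list alone, and 1 lower, camera adjusted p = 2.22e-08, adjusted p = 0.355 with an estimated correlation; 6 higher and 1 lower of 23 in the first set), among them SOD2, the mitochondrial superoxide dismutase (4.76 ± 0.54). Matrix remodelling genes rose in 13 of 20 and fell in 1 (14 adjusted over the list alone, and 1 lower, median 3.93, camera adjusted p = 1.12e-06, adjusted p = 0.186 with an estimated correlation) and in 10 of 18 within the first set. The collagenase MMP1 had a ratio of 575 (197 to 2790) and the matrilysin MMP7 rose by 8.82 ± 1.34. CC chemokines rose in 9 of 17 (9 adjusted over the list alone), with a median of 4.90, or 4.56 with 3 members held at their bounds (camera adjusted p = 2.52e-05, adjusted p = 0.355 with an estimated correlation), and 5 higher and 0 lower of 14 in the first set. CYP27B1, which activates vitamin D, rose by 6.97 ± 0.77, the lysosomal protease CTSL by 5.86 ± 1.12, and the amine oxidase MAOA, a monocyte-derived dendritic cell marker, by 10.06 ± 1.43. Pro-inflammatory cytokines rose in 11 of 21 and fell in 1 (12 adjusted over the list alone, and 1 lower, adjusted p = 0.671 with an estimated correlation), but within the first set 2 of 18 rose and 3 fell.

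Falls in mDC included immediate early genes and markers of other blood cells. FOS fell by −6.18 ± 0.54, FOSB by −6.95 ± 0.72 and NR4A2 by −5.40 ± 0.35, all rapid response transcription factors. The immediate early list fell in 12 of 22 and rose in 3 (12 adjusted over the list alone, and 3 higher, adjusted p = 0.355 with an estimated correlation; 1 higher and 11 lower of 22 in the first set). B cell markers fell in 12 of 13 (12 adjusted over the list alone, median −4.18, camera adjusted p = 1.56e-07, adjusted p = 0.355 with an estimated correlation), and in 9 of 12 in the first set. MS4A1 (CD20) fell by −5.23 ± 0.76 and PAX5, a B cell transcription factor, by −5.38 ± 0.70. Markers of T cells (7 of 17 lower, 7 adjusted over the list alone, adjusted p = 0.691 with an estimated correlation) and of platelets and red cells (7 of 8 lower, 7 adjusted over the list alone, and 1 higher, adjusted p = 0.671 with an estimated correlation) also fell over all libraries. That held for 0 of 17 T cell and 3 of 7 platelet and red cell markers in the first set. Hemoglobin HBB owed its mean of 33790 ± 67580 CPM in cells alone to 1 library. CLEC9A, a marker of the cDC1 dendritic cell subset, fell by −5.56 ± 0.79, and 8 of 14 cDC1 markers fell (8 adjusted over the list alone, adjusted p = 0.186 with an estimated correlation), with 4 of 14 in the first set. Ribosomal protein genes fell in 27 of 30 (29 adjusted over the list alone, median −1.21, camera adjusted p = 3.77e-09, adjusted p = 0.610 with an estimated correlation) and in 8 within the first set. In total 6405 of 19168 genes passed, 2717 higher and 3688 lower, with 2133 and 3154 at 2-fold or more. Processed pseudogenes were 180 of the higher and 126 of the lower calls, against 18 and 38 in the first set. In the first set alone 2808 of 15561 passed (1292 higher, 1516 lower), 2360 of the 6405 among them. With separate cells alone for each set, 77.0% or 77.4% of the genes called in the second had the same sign in the first, against 53.4% or 53.1% of genes with an adjusted p over 0.5. Without the cells alone library numbered 2 or 3 the pooled count was 3771 or 3937.

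Interferon-stimulated genes and inflammatory cytokines were among the genes that rose in moDC. IFI44L, an interferon-induced gene (ENSG00000137959, chromosome 1, 78619922 to 78646145), rose from 2.45 ± 0.711 CPM in cells alone (n = 5) to 263 ± 258 CPM with strains (n = 18). Its log2 fold change was 6.52 ± 1.13 (adjusted p = 0.00136), and the antiviral RSAD2 rose by 5.67 ± 1.21. Of 35 interferon-stimulated genes 31 rose and 0 fell (32 adjusted over the list alone), median 2.62, camera adjusted p = 5.16e-19, adjusted p = 0.148 with an estimated correlation; within the first set 29 rose with a median of 2.24. Interferon-gamma response genes rose in 15 of 18 (17 adjusted over the list alone, median 4.03, adjusted p = 0.117 with an estimated correlation; 16 higher and 1 lower of 18 in the first set), and IFNG itself, a product of T and NK cells, by 7.52 ± 1.32. T cell markers were higher with the strains in 3 of 17 (6 adjusted over the list alone, median 1.40, adjusted p = 0.210 with an estimated correlation; 1 higher and 0 lower of 17 in the first set) and NK cell markers in 1 of 14 (0 adjusted over the list alone, median 0.78, adjusted p = 0.456 with an estimated correlation; 2 higher and 0 lower of 14 in the first set). Without the cells alone library numbered 1, 16 T cell markers passed, all higher. For them that library lay at a median position of 1.15, from 0 at the other cells alone to 1 at the strain libraries. IL12B rose by 9.73 ± 1.75, IL6 by 7.33 ± 1.23, IL1B by 6.57 ± 1.36 and TNF by 4.25 ± 0.71, and PTGS2, the inducible cyclooxygenase, by 7.33 ± 1.53. Pro-inflammatory cytokines rose in 10 of 19 and fell in 1 (14 adjusted over the list alone, and 1 lower), median 2.96, camera adjusted p = 4.19e-09, and adjusted p = 0.0175 with an estimated correlation, which did not pass in the first set (10 higher and 0 lower of 15 in the first set, adjusted p = 0.0854 with an estimated correlation). Within the first set IL6 stood at 9.22 ± 1.54, IL1B at 8.11 ± 0.88 and TNF at 4.37 ± 0.89, and IL12B passed with an adjusted p of 0.00405.

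Chemokines and maturation genes rose as well in moDC. CXC chemokines rose in 9 of 11 and fell in 1 (9 adjusted over the list alone, and 1 lower, median 4.46, adjusted p = 0.0208 with an estimated correlation; 10 higher and 0 lower of 10 in the first set), among them CXCL1 (8.44 ± 1.02) and CXCL8 (6.58 ± 0.71). CC chemokines rose in 8 of 18 (11 adjusted over the list alone, adjusted p = 0.00429 with an estimated correlation; 7 higher and 4 lower of 15 in the first set), with CCL20, which draws CCR6-bearing lymphocytes, at 7.21 ± 1.81. Maturation genes rose in 20 of 27 (23 adjusted over the list alone, median 2.24, camera adjusted p = 2.99e-18, adjusted p = 0.0208 with an estimated correlation; 19 higher and 1 lower of 27 in the first set). NF-kB targets rose in 19 of 23 (22 adjusted over the list alone, median 2.02, camera adjusted p = 7.87e-20, adjusted p = 0.0208 with an estimated correlation; 20 higher and 0 lower of 23 in the first set). Examples were the costimulatory genes TNFRSF4 (4.84 ± 0.55) and CD80 (3.54 ± 0.56), the checkpoint ligand CD274 (3.60 ± 0.51) and the NF-kB inhibitor NFKBIA (3.10 ± 0.42). CD83 rose by 1.67 ± 0.38 over all libraries and stood at 1.34 ± 0.45 (adjusted p = 0.0524) within the first set, where CCR7 rose by 3.25 ± 0.72 against 1.85 ± 0.74 (adjusted p = 0.0994) over all libraries. None of these lists passed with an estimated correlation in the first set of moDC: the adjusted p was 0.0854 for CXC chemokines, 0.155 for CC chemokines and for maturation genes, and 0.127 for NF-kB targets. TAP1, which carries peptides to MHC class I, rose by 2.55 ± 0.57.

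Genes that fell in moDC included PDK4, a brake on pyruvate oxidation (−6.39 ± 0.63) and the adenosine receptor ADORA3 (−4.48 ± 0.43). Oxidative phosphorylation genes fell in 7 of 31 (10 adjusted over the list alone, and 1 higher, median −0.38, camera adjusted p = 2.51e-05, adjusted p = 0.383 with an estimated correlation; 1 higher and 4 lower of 31 in the first set). Lysosomal and phagocytic genes fell in 4 of 31 (6 adjusted over the list alone, adjusted p = 0.456 with an estimated correlation; 5 higher and 6 lower of 31 in the first set), among them the scavenger receptor STAB1 (−1.63 ± 0.34, and −1.44 ± 0.60 with adjusted p = 0.107 in the first set). Over all libraries CD1A (1.63 ± 1.74, adjusted p = 0.571) and CD1C (0.59 ± 1.25, adjusted p = 0.795), lipid antigen presenters of monocyte-derived cells, did not pass, but within the first set they stood at −8.08 ± 1.03 and −5.54 ± 0.80. There all moDC strain libraries are numbered 1, with CD1A at 0.281 to 2.46 CPM. Cells alone number 1 was low as well, with CD1A at 2.93 CPM against 155 to 382 CPM in numbers 2 to 5. Monocyte-derived dendritic cell markers as a list fell in 19 of 21 in the first set (median −3.37, camera adjusted p = 4.40e-12, adjusted p = 0.127 with an estimated correlation) and in 1 of 21 over all libraries, where 1 rose. Monocyte and macrophage markers had 8 higher and 1 lower of 18 in the first set (median 2.19, camera adjusted p = 0.000218, adjusted p = 0.360 with an estimated correlation) and 0 and 1 of 19 over all libraries. Strains and number were not told apart for any first-set value of moDC. In total 2637 of 19331 genes passed, 1373 higher and 1264 lower, with 1212 and 696 at 2-fold or more. Processed pseudogenes were 294 of the higher and 31 of the lower calls, against 27 and 18 in the first set. Among first-set libraries 2988 of 14570 passed (1534 higher, 1454 lower), 978 of the 2637 among them. With separate cells alone for each set, 45.1% or 64.8% of the genes called in the second had the same sign in the first, against 49.5% or 50.4% of genes with an adjusted p over 0.5, so 1 of the 2 splits showed no match of signs. Cells alone 2 and 5, the closest pair of moDC alone, lay in opposite parts of these splits, so the parts were not fully independent. Without the cells alone library numbered 3, 4 or 5 the pooled count was 1318, 1429 or 1687.

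**Figure D2:**
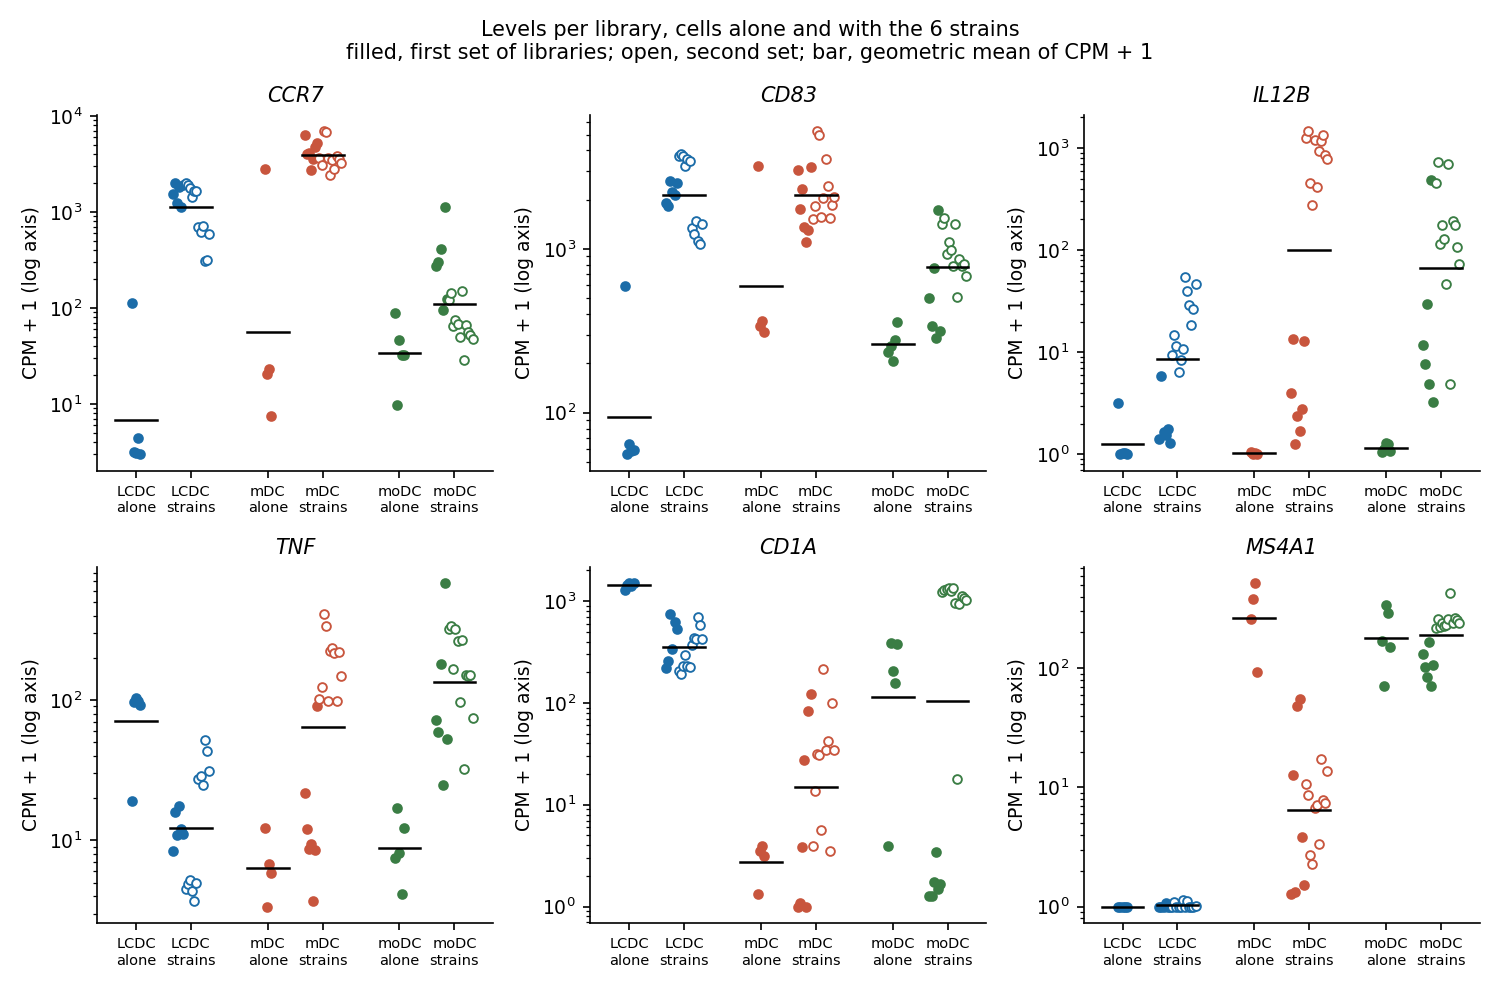
Level of CCR7, CD83, IL12B, TNF, CD1A and MS4A1 in each library as CPM + 1 on a log scale, by cell type and culture; filled points are libraries of the first set, open points those of the second, and bars are geometric means. In moDC with strains, CD1A is low in the first set and high in all but 1 library of the second.

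Genes that passed with 1 sign for each of the 6 strains were counted as changes common to the strains. A set, donor or culture difference from the cells alone would also appear in all 6 and was not told apart. In LCDC 1959 genes did so (1397 higher, 562 lower), among them CCR7, CD83, CCL22 and IDO1, and 20 of 27 maturation genes and 16 of 23 NF-kB targets were higher for all 6. In mDC 937 genes did (611 higher, 326 lower), with IL12B, IL1B and CXCL8 higher for all 6 strains and 9 of 20 matrix remodelling genes and 5 of 27 maturation genes higher for all 6. In moDC 46 genes did (44 higher, 2 lower), among them the chemokines CXCL1, CXCL8 and CCL8, the cytokine IL1A, NFKBIA, CD274 and TNFRSF4. Counts for single strains ran from 2652 (5PA1) to 3812 (110PA3) in LCDC, from 1740 (5PA1) to 3192 (110PA3) in mDC, and from 49 (96PA1) to 967 (110PA3) in moDC. All 6 comparisons share the cells alone, which alone raises the overlap. Simulated unchanged groups against those cells gave 0 shared genes in each cell type, and independent lists of these sizes would share at most 0.038. Drawn from means, library sizes and spreads, the simulation carried no pairing by number and no difference between the 2 sets. Independent lists leave out the shared cells alone as well, so neither value weighs these sources of overlap. With the cells alone split between the strains, 606 genes were shared in LCDC, 91 in mDC and 2 in moDC. In LCDC each part of that split held near copies from numbers 2 to 5. That split therefore could not remove the overlap due to shared cells alone there. In moDC numbers 2 and 5, the closest pair of cells alone, also lay in opposite parts. In the first set alone 1046, 6 and 0 genes passed for all 6 strains. It holds 1 library per strain (2 for 110PA3 in mDC), so the spread came almost wholly from the cells alone. Those counts do not weigh a strain against the spread of its own replicates. Leaving out 1 library moved these counts to as few as 863 in LCDC (without 5PA1 number 2), 335 in mDC (without cells alone number 2) and 11 in moDC (without 96PA1 number 3), and to as many as 2740, 2807 and 209 without cells alone number 1.

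Some changes were common to the 3 cell types. Of 16662 genes tested in all, 294 rose in each type against 32.9 for independent lists, and 162 fell in each against 35. The 3 types share the difference between the 2 sets of libraries, which independent lists leave out. Of the 15 shared higher genes with the largest folds, 9 were processed pseudogenes, such as TXNP6 and ACTBP2. Genes of that class set the 2 sets of libraries apart. TNIP3, an NF-kB feedback gene, IL12B and IL1A rose in each over all libraries. The LCDC calls of TNIP3 and IL1A depended on single libraries: TNIP3 stood at 7.09 (adjusted p = 0.0548), 7.04 (adjusted p = 0.0563) and 7.30 (adjusted p = 0.0547) without cells alone 2, 3 or 4. IL1A stood at 4.49 (adjusted p = 0.0717), 4.51 (adjusted p = 0.0718), 4.38 (adjusted p = 0.0762) and 4.59 (adjusted p = 0.0685) without 2, 3, 4 or 5. Within the first set IL12B and TNIP3 were not tested in LCDC and IL1A did not pass in mDC (4.29 ± 1.55, adjusted p = 0.0725). Over all libraries 10 of 27 maturation genes and 10 of 23 NF-kB targets rose in each. INHBA, which encodes activin A (4.33 ± 1.30 in LCDC, 9.66 ± 2.09 in mDC and 5.69 ± 0.81 in moDC), and ITGB8, an activator of TGF-beta (4.64 ± 0.57, 8.30 ± 1.12 and 4.64 ± 0.83), rose in each. Both, with the genes in the next sentence, were chosen after their values were seen. PDK4, ADORA3, the scavenger receptor MSR1 (−2.54 ± 0.63, −3.55 ± 0.57 and −2.07 ± 0.47) and the leukotriene receptor CYSLTR1 (−2.41 ± 0.12, −2.83 ± 0.44 and −2.18 ± 0.48) fell in each, although MSR1 did not pass in moDC in the first set (−1.82 ± 0.69, adjusted p = 0.0777) nor in LCDC without cells alone number 1 (−1.08 (adjusted p = 0.175)). No interferon-stimulated gene of the 35 moved 1 way in all 3 types, and 7 passed in opposite directions. Without the cells alone library numbered 1, 10 interferon-stimulated genes passed in LCDC, 9 of them higher, and 15 passed in mDC, all higher. For these genes that library lay at median positions of 1.24 and 2.18, from 0 at the other cells alone to 1 at the strain libraries.

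Acne-associated strains (43PA1, 5PA1 and 96PA1) were set against healthy-associated strains (110PA3, 110PA4 and 42PA3) to ask whether the response depends on the kind of strain. No gene passed in any cell type. In moDC the neutrophil attractant CXCL1 lay at 11.6 ± 6.30 CPM with acne-associated (n = 9) and 40.7 ± 42.1 CPM with healthy-associated strains (n = 9). The log2 difference was −1.77 ± 0.53 (adjusted p = 1), and CXCL8 differed by −1.31 ± 0.44 (adjusted p = 1). CXC chemokines had a median difference of −1.20 in moDC, with 0 passing over all genes and 2 lower adjusted over the list alone (camera adjusted p = 0.000102, adjusted p = 0.318 with an estimated correlation). Interferon-stimulated genes had a median of −0.86 in moDC (camera adjusted p = 1.48e-14, adjusted p = 0.318 with an estimated correlation) and of −0.72 in mDC (camera adjusted p = 1.13e-15, adjusted p = 0.887 with an estimated correlation), with 0 of 35 passing in either, 0 adjusted over the list alone. By number 1, 2 and 3 the medians were −0.51, −2.31 and −0.30 in mDC, −0.49, −1.15 and −0.08 in moDC and 0.17, −0.15 and 0.48 in LCDC. The mDC value was carried by number 2, where 110PA3 is in the first set and the other strains in the second. Cholesterol synthesis genes (median 0.28, adjusted p = 0.318 with an estimated correlation) and MHC class II genes (median 0.26, 0 passing, 1 adjusted over the list alone, adjusted p = 0.126 with an estimated correlation) went the other way in moDC. In LCDC CCR7 differed by −0.20 ± 0.72, CD83 by −0.05 ± 0.48 and IDO1 by 0.05 ± 0.41, and in mDC IL12B differed by 0.23 ± 1.27 and IL1B by −0.25 ± 0.85 (adjusted p = 1 for all). The count of 0 from edgeR compares with 108 genes in LCDC, 284 in mDC and 121 in moDC at an unadjusted p under 0.05, and with 0, 0 and 0 from DESeq2. The unadjusted counts were 0.6%, 1.5% and 0.6% of the genes tested, below the share of 0.05 that chance alone would give. The unblocked test left differences between replicate numbers in its spread, so its 0 does not show that the strains act alike. With the replicate number as a block, which pairs the strain libraries in LCDC and moDC, the count stayed 0 in each cell type. It was 60 in moDC with numbers 2 and 3 blocked and 110PA4 number 3 left out, and 7 among LCDC libraries numbered 2, both chosen after the results were seen. Gene lists past the camera test with the preset correlation numbered 0 in LCDC, 9 in mDC and 19 in moDC without the block. With the block they numbered 2, 7 and 21.

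A test of any difference among the 6 strains gave 0 genes with edgeR in each cell type (18 genes in LCDC, 388 in mDC and 66 in moDC at an unadjusted p under 0.05; DESeq2 gave 0, 20 and 0). These unadjusted counts were 0.1%, 2% and 0.3% of the genes tested, again below the share of 0.05. The genes with the lowest p did not pass: UTS2, a vasoactive peptide gene, in LCDC, the protease inhibitors SLPI and PI3 in mDC, and SIGLEC12 in moDC, all with an adjusted p of 1. SLPI averaged 7.80 ± 12.4 CPM (SD, n = 3) in mDC with 110PA3 and 0.0951 to 0.240 CPM with the other strains. Blocking on the number gave 1 gene in LCDC and 0 in mDC and moDC.

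Cells alone were compared to describe the 3 starting populations. LCDC alone differed from moDC alone by Langerhans cell markers, proliferation and granule genes. CD207, langerin, lay at 3193 ± 933 CPM in LCDC (n = 5) and 5.01 ± 4.48 CPM in moDC (n = 5), a log2 difference of 9.31 ± 1.11 (adjusted p = 4.85e-05), and CD1A differed by 2.66 ± 0.77. Langerhans cell markers were higher in 11 of 17 (12 adjusted over the list alone, and 1 lower, camera adjusted p = 8.86e-08, adjusted p = 0.0188 with an estimated correlation). They included the epithelial adhesion gene EPCAM (ratio 493, 95% counting interval 168 to 2390, against 3 counts). Cell cycle genes were higher in 24 of 27 (25 adjusted over the list alone, median 2.99, adjusted p = 0.302 with an estimated correlation), for example CDK1 (4.94 ± 0.42). Markers of neutrophils and mast cells were higher in 12 of 16 (12 adjusted over the list alone, and 1 lower, adjusted p = 0.0188 with an estimated correlation). Among them the stem cell factor receptor KIT differed by 6.77 ± 0.65, the eosinophil peroxidase EPX by a ratio of 15300 (2740 to 604000, against 1 count) and neutrophil elastase ELANE by a ratio of 12800 (2290 to 504000). MoDC alone had more of B cell markers (12 of 13, 12 adjusted over the list alone, adjusted p = 0.318 with an estimated correlation) and T cell markers (14 of 17, 14 adjusted over the list alone, adjusted p = 0.564 with an estimated correlation). They were also higher for glycolysis genes (16 of 24, 18 adjusted over the list alone, adjusted p = 0.411 with an estimated correlation) and lysosomal genes (17 of 31, 18 adjusted over the list alone, and 1 higher, adjusted p = 0.411 with an estimated correlation). CD209 (DC-SIGN) differed by −7.75 ± 0.93, the lipoxygenase ALOX15 by −10.94 ± 1.33 and the lysosomal lipase LIPA by −4.44 ± 0.60. Of 16757 genes, 4551 passed (2104 higher in LCDC, 2447 higher in moDC), and with the LCDC cells alone 2 to 5 summed 1161 did.

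Against mDC alone, LCDC alone were again higher for CD1A (9.35 ± 1.17), CD207 (8.15 ± 1.18) and cell cycle genes (25 of 27, 25 adjusted over the list alone, adjusted p = 0.131 with an estimated correlation). They were also higher for the complement gene C1QC (11.57 ± 0.88) and the membrane protease MMP14 (7.02 ± 0.61). Langerhans cell markers were higher in 9 of 17 (10 adjusted over the list alone, adjusted p = 0.0806 with an estimated correlation). Interferon-stimulated genes were lower in LCDC in 31 of 34 (34 adjusted over the list alone, median −5.24, camera adjusted p = 3.26e-07, adjusted p = 0.462 with an estimated correlation) and NF-kB targets in 16 of 22 (17 adjusted over the list alone, adjusted p = 0.313 with an estimated correlation). Neither list was tested without the mDC cells alone library numbered 1, although single interferon-induced and NF-kB genes turned sign without it. Immediate early genes were lower in 16 of 22 with 1 higher (16 adjusted over the list alone, and 2 higher, adjusted p = 0.131 with an estimated correlation), FOS by −5.90 ± 0.89. B cell markers were lower in all 13 of 13 (13 adjusted over the list alone, median −9.51, or −9.27 with 2 members held at their bounds, adjusted p = 0.131 with an estimated correlation). Plasmacytoid dendritic cell markers were lower in 11 of 13 with 1 higher (12 adjusted over the list alone, and 1 higher, adjusted p = 0.0806 with an estimated correlation). In all 5353 genes passed, 2344 higher and 3009 lower in LCDC, and 1785 with the LCDC cells alone 2 to 5 summed. Without the mDC cells alone library numbered 1, CCL22 went from −3.85 ± 1.88 to 7.74 (adjusted p = 3.13e-05), and TNFSF10, an interferon-induced death ligand, from −3.77 ± 1.25 to 0.64 (adjusted p = 0.488).

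Some lipid, matrix and monocyte-derived genes lay far higher in moDC alone than in mDC alone. DCSTAMP, which drives cell fusion, differed by a ratio of 2560 (95% counting interval 709 to 21200, against 2 counts). The matrix protein FN1 differed by a log2 difference of 12.44 ± 1.68, lipoprotein lipase LPL by 12.14 ± 1.41, CD209 by 7.52 ± 1.02 and the mannose receptor MRC1 by 5.92 ± 0.86. Monocyte-derived dendritic cell markers were higher in 18 of 21 and lower in 1 (18 adjusted over the list alone, and 1 lower, median 6.69, camera adjusted p = 7.17e-13, adjusted p = 0.135 with an estimated correlation). Lysosomal genes were higher in 18 of 31 (20 adjusted over the list alone, and 1 lower, adjusted p = 0.161 with an estimated correlation) and lipid handling genes in 10 of 21 (10 adjusted over the list alone, adjusted p = 0.135 with an estimated correlation). MDC alone were higher for antimicrobial proteins (11 of 14 with 1 higher in moDC, 11 adjusted over the list alone, and 2 higher, adjusted p = 0.348 with an estimated correlation), with lactoferrin LTF at −9.07 ± 0.98. They were also higher for interferon-stimulated genes (24 of 34, 29 adjusted over the list alone, adjusted p = 0.753 with an estimated correlation), for NFKBIZ (−3.33 ± 0.35) and for CLEC4C, a plasmacytoid dendritic cell marker (−5.90 ± 0.46). In all 5032 genes passed, 2286 higher and 2746 lower in moDC. The mDC cells alone library numbered 1 weighed on the interferon genes: IFIT1 differed by −6.27 ± 1.96 over all libraries and by 1.71 (adjusted p = 0.227) without it.

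The response to the strains itself differed between the cell types, as tested by the difference of the fold changes. LCDC against moDC, TNF differed by −6.66 ± 1.22 (adjusted p = 0.000441), NR4A2 by −6.34 ± 0.73 and IFI44L by −7.93 ± 1.63. CCR7 differed by 3.82 ± 1.18, CCL22 by 5.25 ± 1.62 and the actin regulator MARCKSL1 by 3.25 ± 0.68 in favour of LCDC. CCR7 stood at 2.82 (adjusted p = 0.223) in the first set. Without the LCDC cells alone library numbered 3 CCR7 stood at 3.56 (adjusted p = 0.0843) and CCL22 at 5.23 (adjusted p = 0.0741). Interferon-stimulated genes responded less in LCDC in 18 of 35 (28 adjusted over the list alone, median −3.23, camera adjusted p = 1.95e-09, adjusted p = 0.948 with an estimated correlation). LCDC against mDC, TNF differed by −6.75 ± 1.35, IL12B by −8.99 ± 2.94, MMP14 by −8.87 ± 1.32, MMP7 by −7.96 ± 1.56 and FOS by 5.79 ± 1.03. Without the LCDC cells alone library numbered 1 IL12B stood at −4.77 (adjusted p = 0.644), and in the first set at −5.54 (adjusted p = 0.117). Ribosomal protein genes differed in 29 of 30, all higher in LCDC (30 adjusted over the list alone, median 1.78, camera adjusted p = 2.76e-17, adjusted p = 0.389 with an estimated correlation). Immediate early genes differed in 15 higher and 3 lower of 22 (16 adjusted over the list alone, and 3 lower, adjusted p = 0.278 with an estimated correlation). B cell markers differed in 10 of 13 higher (10 adjusted over the list alone, adjusted p = 0.125 with an estimated correlation) and matrix genes in 8 lower and 1 higher of 20 (9 adjusted over the list alone, and 1 higher, adjusted p = 0.310 with an estimated correlation).

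MoDC against mDC, the difference was 8.14 ± 1.65 for IFI44L, 7.31 ± 1.51 for RSAD2 and 6.74 ± 1.86 for IDO1, all responding more in moDC. It was −11.76 ± 1.95 for CCL24, −6.65 ± 1.49 for MMP7 and −6.42 ± 1.31 for CTSL, all responding more in mDC. Without the mDC cells alone library numbered 1 RSAD2 stood at 0.55 (adjusted p = 0.786) and IDO1 at 0.46 (adjusted p = 0.891). Interferon-stimulated genes responded more in moDC in 27 of 35 (31 adjusted over the list alone, median 3.71, camera adjusted p = 0.000639, adjusted p = 0.774 with an estimated correlation). This list was not tested without the mDC cells alone library numbered 1, on which the difference of its member RSAD2 rested. Lysosomal genes responded less in 11 of 31 (13 adjusted over the list alone, and 2 higher, adjusted p = 0.616 with an estimated correlation). T cell markers (11 of 17, 15 adjusted over the list alone, adjusted p = 0.254 with an estimated correlation) and B cell markers (11 of 13, 12 adjusted over the list alone, adjusted p = 0.228 with an estimated correlation) differed along with them. Of 22040 genes, 1648 passed for LCDC against moDC (919 higher, 729 lower), 4276 for LCDC against mDC (2451 and 1825) and 4961 for moDC against mDC (2786 and 2175). In the first set alone 2585 (1449 and 1136), 3810 (2056 and 1754) and 3773 (1832 and 1941) passed, of which 951, 2475 and 2534 also passed over all libraries. With the LCDC cells alone 2 to 5 summed, 108 genes passed for LCDC against moDC and 1496 for LCDC against mDC. The count for LCDC against moDC was 1070 without LCDC cells alone number 3, 1097 without number 5 and 1085 without moDC cells alone number 4.

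**Figure D3:**
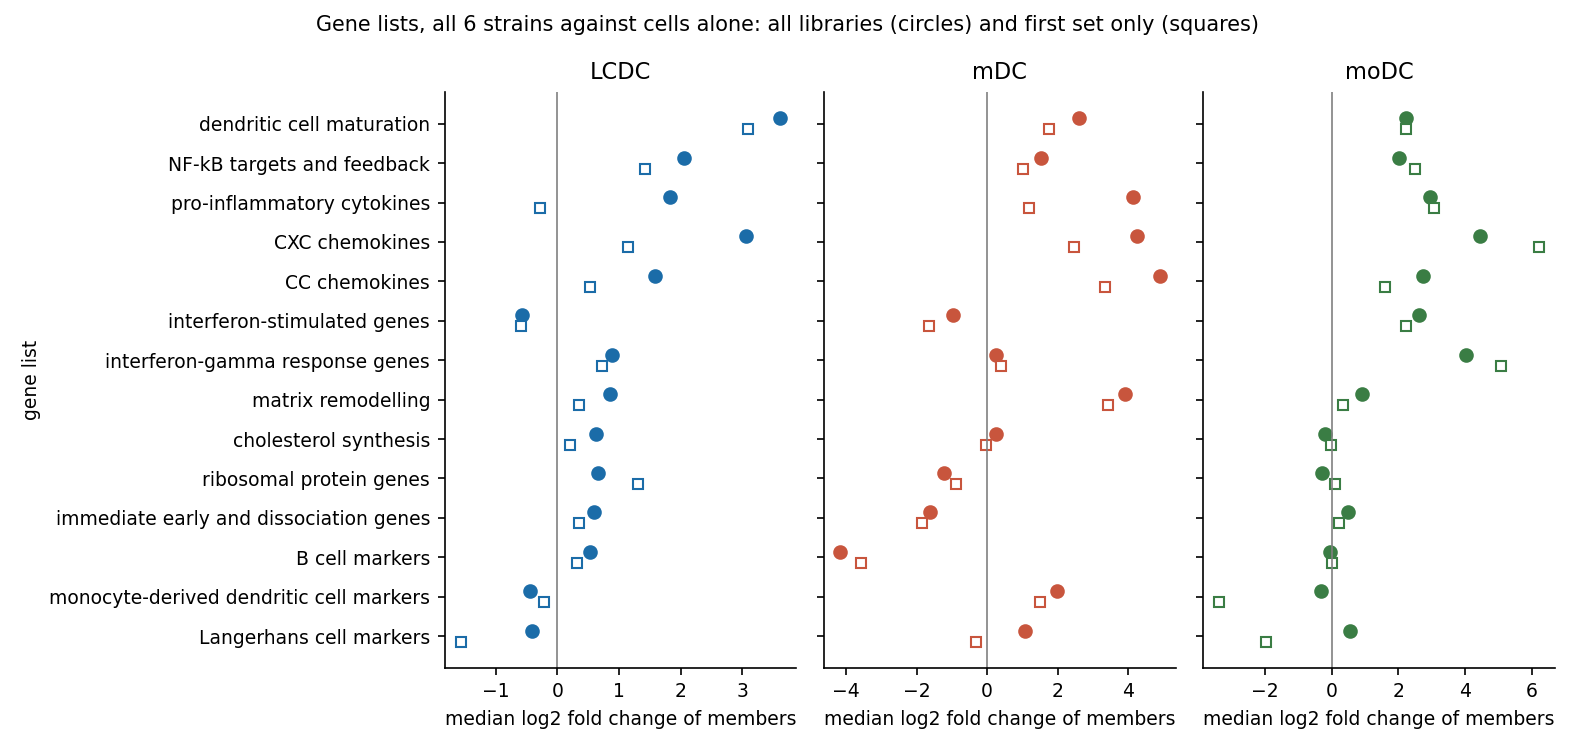
Median log2 fold change of 14 gene lists with all strains against cells alone in LCDC, mDC and moDC; circles use all libraries and squares the first set only. The interferon-stimulated list lies at 2.62 in moDC and below 0 in LCDC and mDC, and B cell markers lie at −4.18 in mDC.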

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

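Tests of the 2 sets of libraries, of the cells alone library numbered 1 and of B against T cell markers were chosen only after the result was seen. Thinning and tests within 1 replicate number were added after other results were seen but before their own, and the remaining tests were chosen before.

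The cells alone library numbered 1 stood apart from the others of its type. In LCDC (n = 5) it was highest for CCR7 (113 CPM), CD83 (590 CPM), CCL22 (145 CPM), IDO1 (115 CPM), CD1C (520 CPM), CD209 (4.14 CPM), IL12B (2.17 CPM), IL10 (0.723 CPM) and the share of mitochondrially encoded genes (15%), and lowest for CD207 (1390 CPM), IL1B (34.4 CPM), CD80 (27.2 CPM) and TNF (18.1 CPM). In mDC (n = 4) it was highest for CCL22 (4050 CPM), CD83 (3220 CPM), CCR7 (2840 CPM), IDO1 (2470 CPM), CD80 (109 CPM), CD207 (25.6 CPM) and IL1A (0.963 CPM). In moDC (n = 5) it was highest for CCL20 (0.608 CPM) and had the lowest total (14.6 M counts). Elsewhere, mDC cells alone number 3 was highest for CD14 (273 CPM) and moDC cells alone number 4 for CCL22 (6890 CPM). In all, 24 far values were found in 69 groups of values tested, where chance gives about 1 in 20.

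The response to the strains differed between cell types by a test of the difference itself, with 1648 genes for LCDC against moDC, 4276 for LCDC against mDC and 4961 for moDC against mDC. Among genes always reported, LCDC less moDC gave log2 differences of −6.66 for TNF, −6.25 for CCL20, −4.07 for CD80, −3.70 for CXCL8, 5.25 for CCL22, 3.82 for CCR7 and 2.11 for CD83. LCDC less mDC gave −8.99 for IL12B, −6.75 for TNF, −5.96 for CCL20, −5.87 for CD1A, −4.30 for CD80 and 2.66 for CD83. MoDC less mDC gave 6.74 for IDO1 and −6.00 for IL10. Some of these calls were lost in settings given in the Results. They were CCR7 and CCL22 without LCDC cells alone number 3, CCR7 and IL12B in the first set, IL12B without LCDC cells alone number 1, and IDO1 without mDC cells alone number 1. CD83 in mDC alone lay at 3222 CPM in number 1 and at 308 to 364 CPM in the others, so its difference from mDC leaned on 1 library.

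Many genes passed between strains and cells alone, in libraries that group by replicate number and by set. A difference in depth was argued against as the whole cause: after thinning to the smallest total at least 73.9% of the number of calls was left in each cell type. A difference between the 2 sets of libraries stays open as a contributor, since among genes called in the second set the share with the same sign in the first was as low as 45.1% (moDC, against 1 part of the cells alone, where genes with an adjusted p over 0.5 gave 49.5%) and as high as 84.7% (LCDC). In LCDC both parts of the cells alone held near copies of each other, so they were not independent. In moDC the closest pair of cells alone, numbers 2 and 5, also lay in opposite parts. Over the genes called without it, the cells alone library numbered 1 lay at a median position of up to 0.80 (mDC) between the other cells alone and the strain libraries, and in each cell type 1 cells alone library was nearest to a strain library, so a label error, donor, culture or batch may account for part of these calls. Effects of the strains and of these differences cannot be told apart for libraries of the second set, which has no cells alone.

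Markers of B, T and NK cells and of platelets and red cells were lower in mDC with strains than in mDC alone over all libraries, but in the first set 0 of 17 T cell and 1 of 14 NK cell markers passed. A difference in depth was argued against, as the B cell list kept a median of −4.21 after thinning. A single fall in the share of all other blood cells might lower the lists alike, and the mean of the B cell list lay −2.71 (SE 0.46) from that of the T cell list. That SE is over member genes taken as independent and holds no spread between libraries. The difference therefore does not decide against a single fall. RNA of B cells as 1 source of the B cell markers stays open: their median pairwise correlation over the 18 strain libraries was 0.70, at the edge of the value set in advance, with MS4A1 at 305 ± 180 CPM in mDC alone (SD, n = 4). Loss of B cells in culture with the bacteria was not tested.

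Interferon-stimulated genes lay lower with acne-associated than with healthy-associated strains in moDC, with a median of −0.86 and no gene past the test. The library of 110PA4 number 3 does not account for it, since the median without it was −1.04, but leaving out 1 strain library moved the median to between −1.17 and −0.24. Within replicate numbers the medians were −0.49, −1.15 and −0.08, so the difference in libraries numbered 3 is near 0. Of the 10 splits of the 6 strains into 3 and 3, 2 gave a median as far from 0, the real one included, with 0.89 the highest other. With so few strains, the split cannot give a share under 0.05.

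Other splits of the same libraries were counted for each comparison, 100 per comparison and 24 for the differences in response. For the strains against cells alone, only 1 split, the real one, gave as many genes: 7064 against at most 3078 in LCDC, 6405 against 6110 in mDC and 2637 against 1164 in moDC. For all 6 strains the highest other counts were 26, 6 and 0. For cells alone they were 1389 (LCDC against moDC), 763 (LCDC against mDC) and 3525 (moDC against mDC), and for the response 194, 651 and 283 in the same order, below the real counts each time, so chance can be excluded for these only as far as libraries are interchangeable. The pairing by number, the near copies among LCDC alone and the 2 sets break that, and in mDC another split came near the real count. For acne-associated against healthy-associated strains the real count was 0, which all 100 splits meet by design, so they decide nothing (edgeR; 108, 284 and 121 at an unadjusted p under 0.05; DESeq2 0, 0 and 0), with up to 4385, 306 and 6449. For any difference among strains all 100 did too (18, 388 and 66 at an unadjusted p under 0.05; DESeq2 0, 20 and 0), with up to 5279, 1133 and 1770. Splits with so many genes point to a structure of the libraries that the strains do not explain.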

How the results depend on the processing

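Normalization, tool, filter, replicate block and left-out libraries were chosen before the data were examined; the summed LCDC cells alone, libraries of 1 number, the 2 sets and thinning were tests chosen after the results were seen, although thinning was chosen before its own values were. The planned comparison of count columns was not possible, since each library has a single column.

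With RLE size factors the count of each comparison stayed within 1.5 times the value reported and no named gene changed sign. The same held with thinning to the smallest total for the comparisons within 1 cell type. Comparisons of cells alone between types and differences in response were not thinned. Without the low-count filter 1213 genes passed for all 6 strains in LCDC, 483 in mDC, and 1087 for the response of LCDC against moDC, where more genes are tested. DESeq2 gave 1850 genes for all 6 strains in mDC, 263 in moDC, 4050 for the strains against cells alone in moDC, 20 for any difference among the strains in mDC and 2515 for the response of LCDC against moDC. The replicate block gave 3922 genes for all 6 strains in LCDC and 510 in moDC, 3996 for the strains against cells alone in moDC, and 1 for any difference among strains in LCDC, where the strain libraries are paired. For the acne-associated against healthy-associated strains the paired count stayed 0 in LCDC and moDC. In these cases the cause was not tested.

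With LCDC cells alone 2 to 5 summed into 1, counts fell to 1490 (strains against LCDC alone), 169 (all 6 strains), 1161 (LCDC against moDC alone), 1785 (LCDC against mDC alone), 108 (response, LCDC against moDC) and 1496 (response, LCDC against mDC); fewer libraries then stand for the cells alone. In the first set alone, 1046 genes passed for all 6 strains in LCDC, 6 in mDC and 0 in moDC (edgeR), where 1 library per strain gives no spread of its own, 2808 for strains against cells alone in mDC and 2585 for the response of LCDC against moDC. Only libraries numbered 2 gave 11009 genes in LCDC and 6532 in moDC, those numbered 3 gave 4517 in moDC, and those numbered 1 gave 2228 in mDC. For acne-associated against healthy-associated strains 7 genes passed among LCDC libraries numbered 2, and 60 in moDC with numbers 2 and 3 blocked and 110PA4 number 3 left out. Over the comparisons of strains with cells alone, of strains and of cells alone, 153 list tests passed with a preset correlation and 8 with an estimated one.

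Leaving out 1 library moved the count for all 6 strains to between 863 (without 5PA1 number 2) and 2740 (without cells alone number 1) in LCDC, 335 (cells alone 2) and 2807 (cells alone 1) in mDC, and 11 (96PA1 number 3) and 209 (cells alone 1) in moDC. Strains against cells alone gave 3771 (cells alone 2) to 8101 (cells alone 1) in mDC and 1318 (cells alone 3) to 3420 (43PA1 number 1) in moDC. The response of LCDC against moDC gave 1070 (LCDC cells alone 3) to 2424 (LCDC cells alone 1), with 1097 without LCDC cells alone 5 and 1085 without moDC cells alone 4. For strains against LCDC alone, the cell types alone and the other responses, counts stayed within 1.5 times, and for the comparisons among strains edgeR gave 0 each time (108, 284 and 121 genes at an unadjusted p under 0.05 for acne-associated against healthy-associated strains; 18, 388 and 66 for any difference).

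Signs turned for CD209 in LCDC with libraries numbered 2 (−2.19) and HLA-C with those numbered 3 (−0.09). In moDC they turned for CD14 with the block (−3.84) and with libraries numbered 2 (−7.83) or 3 (−5.04), and with those numbered 1 for FOSB (−0.82), CD1A (−8.08), CD1C (−5.54), CCL22 (−1.76) and CD209 (−1.41). HSPA1A of LCDC against mDC alone turned with the block (1.03). In the response within the first set they turned for CD1A (6.44) and CD1C (5.65) in LCDC against moDC, and for CD1C (−4.05), TLR2 (1.55) and IL23A (4.69) in moDC against mDC. Without the mDC cells alone library numbered 1 signs turned for TRAF1 (−3.46 to 0.88, the range here and below over the left-out libraries that changed a call), HSPA1A (−4.59 to 2.90), HSPA1B (−4.05 to 1.39), TNFSF10 (−3.58 to 0.64), IDO1 (−4.11 to 2.66), CCR7 (−4.99 to 0.52) and CCL22 (7.74) in LCDC against mDC alone, and for IFIT1 (−6.27 to 1.71) and CD80 (2.10) in moDC against mDC alone. In the response they turned without it for CXCL11 (−4.47 to 8.43) and CCL22 (−9.06) in LCDC against mDC, and for CXCL11 (−2.79) and CXCL10 (−3.45) in moDC against mDC. MARCO in LCDC turned without cells alone 1 (1.40), and HBD in mDC without cells alone 2 (0.27).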

Other observations

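Tests within the first set of libraries were chosen only after the results were seen; the other tests were chosen before.

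Further gene groups fixed before the data were examined moved with the strains. Apoptosis genes rose in 10 of 21 in LCDC and fell in 4 (12 adjusted over the list alone, and 4 lower, adjusted p = 0.353 with an estimated correlation; 11 higher and 6 lower of 21 in the first set), and rose in 8 of 22 in moDC and fell in 1 (10 adjusted over the list alone, and 1 lower, adjusted p = 0.117 with an estimated correlation; 9 higher and 0 lower of 21 in the first set). In mDC 4 rose and 7 fell of 22 (5 adjusted over the list alone, and 8 lower; 2 higher and 2 lower of 22 in the first set). Regulatory and tolerance genes rose in 9 of 24 in LCDC and fell in 4 (13 adjusted over the list alone, and 4 lower, adjusted p = 0.436 with an estimated correlation; 11 higher and 5 lower of 22 in the first set). The counts were 9 and 7 of 24 in mDC (10 adjusted over the list alone, and 8 lower; 7 higher and 4 lower of 24 in the first set) and 8 and 1 of 23 in moDC (10 adjusted over the list alone, and 2 lower, adjusted p = 0.117 with an estimated correlation; 8 higher and 1 lower of 23 in the first set). Kynurenine and arginine metabolism, the pathways of IDO1 and arginase, had 6 higher and 2 lower of 15 in LCDC (7 adjusted over the list alone, and 2 lower, adjusted p = 0.496 with an estimated correlation; 7 higher and 3 lower of 12 in the first set), 6 and 1 of 16 in mDC (6 adjusted over the list alone, and 1 lower, adjusted p = 0.186 with an estimated correlation; 3 higher and 0 lower of 14 in the first set) and 4 and 0 of 14 in moDC (6 adjusted over the list alone, adjusted p = 0.117 with an estimated correlation; 9 higher and 0 lower of 13 in the first set). MHC class I presentation genes rose in 8 of 16 in LCDC (8 adjusted over the list alone, adjusted p = 0.396 with an estimated correlation; 7 higher and 1 lower of 16 in the first set), 2 in mDC (1 adjusted over the list alone, adjusted p = 0.671 with an estimated correlation; 0 higher and 0 lower of 16 in the first set) and 4 in moDC (9 adjusted over the list alone, and 1 lower, adjusted p = 0.293 with an estimated correlation; 12 higher and 0 lower of 16 in the first set).

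Stress and marker lists were tested too. Unfolded protein response genes rose in 7 of 23 in LCDC (7 adjusted over the list alone, adjusted p = 0.660 with an estimated correlation; 12 higher and 0 lower of 22 in the first set), hypoxia genes in 7 of 17 with 1 lower (7 adjusted over the list alone, and 2 lower, adjusted p = 0.496 with an estimated correlation; 7 higher and 2 lower of 16 in the first set), and no metallothionein of 9 did in LCDC (0 higher and 2 lower of 5 in the first set), against 2 of 9 in mDC (1 higher and 1 lower of 4 in the first set). In moDC 1 of 10 rose over all libraries (median 5.37, camera adjusted p = 0.0400, adjusted p = 0.567 with an estimated correlation) and 8 of 10 in the first set (median 7.28, camera adjusted p = 1.34e-10, adjusted p = 0.127 with an estimated correlation). Inflammasome genes had 1 higher and 4 lower of 14 in LCDC (3 higher and 4 lower of 12 in the first set), 3 and 6 in mDC (1 higher and 3 lower of 14 in the first set), and 3 and 2 in moDC (6 adjusted over the list alone, and 2 lower, adjusted p = 0.413 with an estimated correlation; 8 higher and 2 lower of 14 in the first set). Monocyte and macrophage markers fell in 8 of 19 in LCDC (8 adjusted over the list alone, adjusted p = 0.660 with an estimated correlation; 1 higher and 7 lower of 17 in the first set), and markers of blood myeloid dendritic cells fell in 10 of 19 and rose in 5 (10 adjusted over the list alone, and 5 higher, adjusted p = 0.496 with an estimated correlation; 6 higher and 8 lower of 19 in the first set). NK cell markers fell in 9 of 14 in mDC (9 adjusted over the list alone, adjusted p = 0.689 with an estimated correlation), but in 1 of 14 in the first set. Keratinocyte and stromal markers had 4 higher and 3 lower of 12 in LCDC (5 adjusted over the list alone, and 3 lower, adjusted p = 0.912 with an estimated correlation; 2 higher and 1 lower of 9 in the first set). Of 13 mitochondrially encoded genes, 1 fell in moDC (1 adjusted over the list alone, adjusted p = 0.456 with an estimated correlation; 0 higher and 0 lower of 13 in the first set).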
